A study of Mus musculus with 21 samples.

How the data were processed

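RNA was sequenced from 21 libraries of sorted C57BL/6 mouse cells in 7 groups of 3. Per the series design, cardiac macrophages came from independent pools of naive mice and of mice given the *Candida albicans* water-soluble complex (CAWS), a fungal cell wall extract that gives mice an arteritis resembling Kawasaki disease, and each pool was divided into 3 populations. Per the labels, R1 is Ccr2-negative and MHC-II-low, R2 is Ccr2-negative and MHC-II-high, and R3 is Ccr2-positive and MHC-II-high, and the monocytes are Ccr2-positive cells from the spleens of naive mice. RNA was isolated with the RNeasy Plus Mini kit and libraries were made with the TruSeq RNA kit, per the labels' protocols.

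The deposited values are counts of reads per gene made with featureCounts on the mouse build mm10, per the submitters' processing notes. Gene length in bases stands beside each gene, per the file headers. The deposited counts are not normalised. The aligner, the annotation release, the strand setting and the version of featureCounts are not given in the sources used here. The per-sample counts were identical to the combined table for 21 of 21 libraries, and the combined table was used.

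The table holds 27179 gene IDs. Symbols and positions were taken from the RefSeq table of assembly GRCm38.p6 by gene ID, which matched 25275 IDs and left 1904 without a symbol. Genes with enough counts in the groups (edgeR's filterByExpr, minimum count 10 and minimum total count 15) were tested, 13275 in all, 278 of them without a symbol. Total counts ran from 12800136 to 23006155 per library, with a median of 16763449. TMM normalisation factors ran from 0.9093 to 1.065. Expression is given as CPM, counts scaled to a common depth, on TMM-adjusted library sizes, as the mean and standard deviation of 3 libraries. Counting error was small beside the replicate spread: the chi-square per degree of freedom between replicates was 9.79 to 128. Where a group held no count of a gene, a floor of 3 counts over the group applies. The floor covers counting error only, while the SD and the SE include the spread between replicates.

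The 16 comparisons were made with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust, newer dispersion method), with 1 mean per group, all 21 libraries sharing the estimate of the spread (14 residual degrees of freedom) and Benjamini-Hochberg adjusted p under 0.05. All tests are two-sided. An interaction is the difference between the CAWS effects of 2 populations, tested as a contrast. Log2 fold changes are given with standard errors worked out from the fold change and its F statistic. The 45 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a comparison, with the correlation estimated from the data as an alternative, and with fry. 8 list members could not be matched to the table. Some genes stand in more than 1 list, so the results of different lists are not independent. The lists, the comparisons, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Alternatives were DESeq2 1.42.0, another scaling, no filter and a stricter filter, the older edgeR fit, limma voom with sample weights, only the groups compared, a replicate term, and each library left out in turn.

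Genes are named by a rule. Ccr2, the MHC class II list, Adgre1 and Csf1r are followed in every group. Each CAWS comparison adds the 10 largest changes in each direction and each other comparison the 6 largest, among genes past the threshold with a mean log2 CPM of at least 4 in the higher group and, outside interactions, with no overlap between replicates; gene models, clones, uncharacterised loci and pseudogenes were left out. Up to 4 members of each list with the smallest p are added, and the text names those of the lists it describes. Gene models that share reads with near-identical copies are uncertain, which holds for the MHC class I genes, the ribosomal proteins with their pseudogenes and the Pira and Ly6 families. Overlapping genes on opposite strands are uncertain as well, as with Zfas1 and Znfx1, since the strand setting is not known.

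Whether replicate numbers pair the libraries was judged from the series design and from the correlation of the libraries' deviations from their group means. The populations of 1 pool carry the same number, per the series design, and same-numbered libraries deviated together within each treatment, with 18 correlations from 0.14 to 0.59. Between treatments, and with the monocytes, correlations ran from -0.24 to 0.65 and 0 of the comparisons had all over 0.1. The number was therefore read as a pool within each treatment and as no pair across treatments. The fit behind the printed p-values had no pool term, and a fit with the pool as a block within each treatment is given as an alternative. In the interactions that block raised the number of genes past the test, so a gene not past the printed test there may pass with it.

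The test was tested on simulated data, counts drawn with the means, library sizes and dispersions of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. For CAWS against naive cells it recovered 65% and 82% in R1, 55% and 83% in R2, and 61% and 88% in R3, and the share of false calls was 10.9%, 3.5% and 8.02%. For the interactions it recovered 33% and 76% (R2 minus R1), 32% and 62% (R3 minus R1) and 43% and 75% (R3 minus R2), and the share of false calls was 7.63%, 6.93% and 5.6%. Shares above the nominal 5% mean that calls close to the threshold are less certain than their adjusted p. The simulated libraries were drawn independently, with no pool effect, and once per comparison. The shares for the interactions may thus differ in these data, where populations share pools.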

Results

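RNA was measured by sequencing in 21 libraries of sorted mouse cells, 3 in each of 7 groups. In 6 groups the cells were cardiac macrophages, sorted as R1 (Ccr2-negative, MHC-II-low), R2 (Ccr2-negative, MHC-II-high) and R3 (Ccr2-positive, MHC-II-high). They came from naive mice and from mice given CAWS, a fungal cell wall extract that brings on an arteritis resembling Kawasaki disease. The seventh group held Ccr2-positive monocytes from the spleens of naive mice. Total counts per library ran from 14140007 to 18980257 in naive R1, from 18013289 to 23006155 in naive R2 and from 15116329 to 17471170 in naive R3. In the CAWS groups they ran from 16484940 to 18970444 in R1, from 15036719 to 19341770 in R2 and from 12800136 to 14630186 in R3. In the monocytes they ran from 16118186 to 18708547. Of the genes, 13275 had enough counts to be tested.

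The surface markers used for sorting were compared with their RNA. Ccr2 is the receptor that brings monocytes into tissue (gene ID 12772, chromosome 9, 124101918 to 124109140 of GRCm38.p6). It measured 6.58 ± 2.04 CPM in naive R1, 29.3 ± 9.25 in naive R2 and 2390 ± 304 in naive R3 (SD, n = 3), against 3262 ± 313 in the monocytes. H2-Ab1 is the beta chain of an MHC class II molecule (gene ID 14961, chromosome 17, 34263227 to 34269418). It measured 605 ± 167 CPM in naive R1, 10610 ± 976 in naive R2, 12270 ± 1400 in naive R3 and 571 ± 277 in the monocytes. Each RNA thus stood in the order of the sort, although R2 held more Ccr2 RNA than R1 (log2 fold change 2.17 ± 0.35, adjusted p = 0.000665). The macrophage gene Adgre1, which encodes F4/80, measured 2074 ± 100 CPM in naive R1 and 1705 ± 37.1 in naive R3 against 579 ± 54.9 in the monocytes. Csf1r, the receptor for the growth factor M-CSF, measured 7941 ± 221 and 5845 ± 372 CPM against 3378 ± 467.

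**Figure D1:**
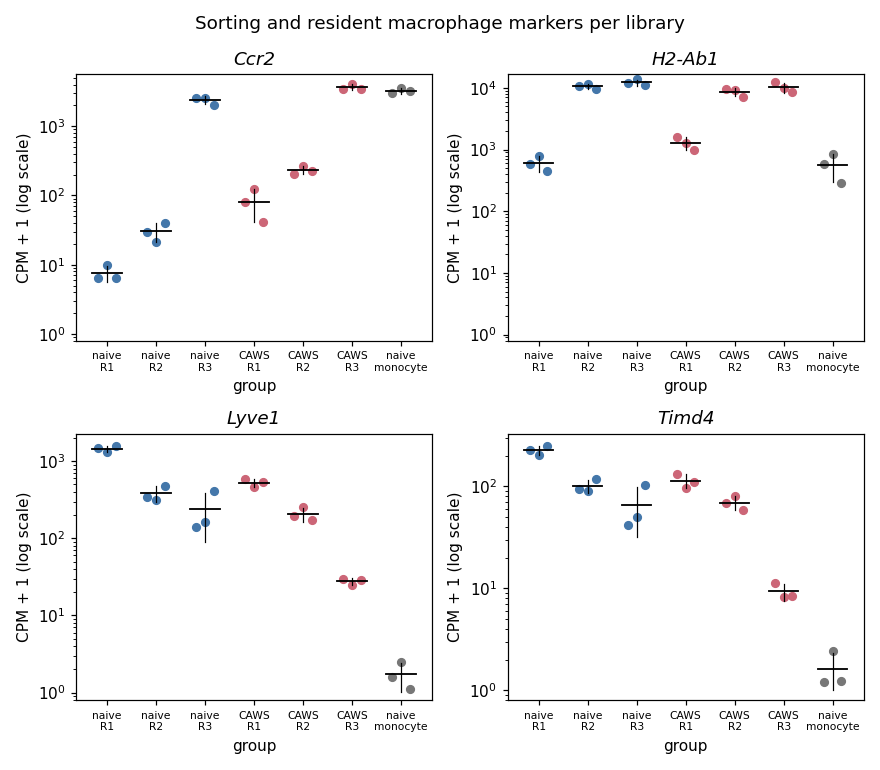
CPM plus 1 on a log scale for Ccr2, H2-Ab1, Lyve1 and Timd4 in the 7 groups; each point is a library, the horizontal line is the mean of 3 libraries and the vertical line is 1 SD to each side, ending at 0 CPM where it would go below. Ccr2 is high in R3 and in monocytes, H2-Ab1 in R2 and R3, and Lyve1 and Timd4 are lower in CAWS R3 than in naive R3.

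CAWS against naive cells was asked first for R1, the Ccr2-negative, MHC-II-low macrophages. Saa3, an acute-phase protein that macrophages make in inflammation (gene ID 20210, chromosome 7, 46711998 to 46719615), went from 0.172 ± 0.257 to 56.3 ± 15.9 CPM (SD, n = 3). Its log2 fold change was 8.43 ± 0.75 (SE, adjusted p = 1.3e-07). The elastin-cutting protease Mmp12 (gene ID 17381, chromosome 9, 7344397 to 7360461) rose from 9.19 ± 4.34 to 116 ± 13 CPM (3.65 ± 0.28, adjusted p = 1.3e-07). The membrane protease Mmp14, which cuts collagen, rose from 8.99 ± 2.10 to 86.9 ± 2.75 CPM (3.27 ± 0.19, adjusted p = 6.21e-10). Itgax, the integrin CD11c of dendritic cells and activated macrophages (gene ID 16411, chromosome 7, 128129526 to 128150657), rose from 8.27 ± 4.56 to 93.7 ± 22.3 CPM (3.46 ± 0.27, adjusted p = 1.3e-07). Ccr2 itself rose from 6.58 ± 2.04 to 80.5 ± 40.5 CPM (3.62 ± 0.35, adjusted p = 6.87e-06), still far below R3. On the log2 scale the leukocyte protease Adam8 rose by 3.01 ± 0.24, the wound-associated cytokine Spp1 (osteopontin) by 2.89 ± 0.33 and the myeloid kinase Fgr by 2.29 ± 0.28. The Fgr call was lost with only the compared groups (adjusted p = 0.0765). The largest falls included Ccn1, a matrix signalling protein (-1.57 ± 0.28, adjusted p = 0.00146), and the lectin Mgl2 (-1.47 ± 0.22, adjusted p = 0.000379). Lyve1, the hyaluronan receptor of resident macrophages, fell as well (-1.45 ± 0.31, adjusted p = 0.00732). Retnla, a marker of alternative activation, fell by 1.37 ± 0.34 (adjusted p = 0.0186), a call lost without naive R1 replicate 3 (adjusted p = 0.082), without CAWS R1 replicate 2 (adjusted p = 0.0832) or replicate 3 (adjusted p = 0.0616) and without the 3 libraries that stood apart (adjusted p = 0.123).

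Among the gene lists in R1, lipid-associated and repair macrophage genes, which foam cells and tissue-repairing macrophages carry, had the smallest p. Of 29, 14 rose, 1 fell and 14 did not pass the test (16 and 1 adjusted over the list alone). The galectin Lgals3 rose by 1.79 ± 0.15 and the tetraspanin Cd9 by 1.39 ± 0.12, and the list median was 0.513 (camera adjusted p = 3.03e-19, and 0.00913 with an estimated correlation). Extracellular matrix, protease and growth factor genes rose in 7 of 29 and fell in 2 (8 and 3 adjusted over the list alone, adjusted p = 0.00913 with an estimated correlation). NF-kB response genes rose in 8 of 23 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.024 with an estimated correlation). Among them the fungal receptor Clec4e (Mincle) rose by 2.93 ± 0.28 and the signalling adaptor Traf1 by 1.40 ± 0.19. Fungal pattern recognition genes rose in 6 of 24 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0151 with an estimated correlation). GM-CSF receptor and response genes rose in 6 of 23 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation), with the lipid-sensing factor Pparg up by 1.24 ± 0.23.

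Genes of antigen presentation were among those higher in R1. MHC class II presentation rose in 6 of 11 genes and fell in 0 (8 and 0 adjusted over the list alone). Its master regulator Ciita went from 26.2 ± 6.02 to 69.8 ± 7.93 CPM (1.41 ± 0.19, adjusted p = 6.07e-05) and H2-Ab1 from 605 ± 167 to 1300 ± 313 CPM (1.10 ± 0.29, adjusted p = 0.026; SD for CPM, SE for log2 fold changes, n = 3). The H2-Ab1 call was lost with no filter on low counts (adjusted p = 0.065), with only the compared groups (adjusted p = 0.0978) and without any of 4 single libraries, the highest being adjusted p = 0.121 without naive R1 replicate 3. MHC class I presentation rose in 11 of 18 and fell in 0 (12 and 0 adjusted over the list alone), with the classical molecule H2-K1 up by 0.82 ± 0.11. Interferon-gamma-induced genes rose in 11 of 29 and fell in 0 (16 and 0 adjusted over the list alone), with the chemokine Cxcl9 up by 1.78 ± 0.25 and the GTPase Gbp2 by 1.43 ± 0.21. These 3 lists passed at adjusted p = 1.27e-08, 3.66e-10 and 3.53e-08 and lost the call (adjusted p = 0.0861, 0.0773 and 0.139 with an estimated correlation). With fry all 3 passed (adjusted p = 0.00137, 0.000235 and 0.00206).

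Genes of other cell types moved in R1 at the same time. NK and cytotoxic markers rose in 5 of 6 and fell in 0 (5 and 0 adjusted over the list alone). T cell markers rose in 2 of 7 and mast cell, basophil and eosinophil markers in 2 of 7, with 0 falls (3 and 0, and 6 and 0, adjusted over the list alone). These lists passed at adjusted p = 1.6e-05, 0.00468 and 0.00504 and lost the call (adjusted p = 0.0773, 0.1 and 0.208 with an estimated correlation). With fry these 3 lists passed (adjusted p = 0.000615, 0.00118 and 0.00169). Some of these genes lay near the floor, and Gzma had no count in naive R1 and 4.06 CPM in CAWS R1. Conventional dendritic cell markers rose in 8 of 22 and fell in 0 (8 and 0 adjusted over the list alone), among them the transcription factor Mycl (1.54 ± 0.24) and the adhesion molecule Cadm1 (0.58 ± 0.12). Their median was 1.38, or 1.12 with the 3 genes that had no count in a group at their floor. Classical monocyte markers rose in 7 of 19 and fell in 0 (9 and 0 adjusted over the list alone), with the integrin Itgb7 up by 2.09 ± 0.44. The Itgb7 call was lost with limma voom (adjusted p = 0.0789) and with only the compared groups (adjusted p = 0.079). Cardiomyocyte genes, which belong to heart muscle, rose in 8 of 22 and fell in 0 (10 and 0 adjusted over the list alone). Cardiac actin Actc1 went from 7.12 ± 1.06 to 14.5 ± 1.82 CPM (1.03 ± 0.24, adjusted p = 0.00765; SD, n = 3), where naive R2 held 18.2 ± 5.06. Resident cardiac macrophage markers fell in 4 of 22 and rose in 0 (7 and 0 adjusted over the list alone), among them Lyve1 and Timd4, a receptor for dying cells, which fell by 1.00 ± 0.25 (adjusted p = 0.0174). The Timd4 call was lost with DESeq2 (adjusted p = 0.0677), without naive R1 replicate 3 (adjusted p = 0.0654), without CAWS R1 replicate 2 (adjusted p = 0.0782) or replicate 3 (adjusted p = 0.0619) and without the 3 libraries that stood apart (adjusted p = 0.0554). The dendritic cell, monocyte, cardiomyocyte and resident lists passed at adjusted p = 1.68e-06, 1.5e-08, 0.000276 and 0.000129. All 4 lost the call (adjusted p = 0.0773, 0.0773, 0.224 and 0.356 with an estimated correlation). With fry the resident list did not pass (adjusted p = 0.128) and the other 3 did (adjusted p = 0.00071, 0.00118 and 0.00528).

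In all, 1187 genes passed the test in R1, 806 higher and 381 lower, of which 319 and 52 changed at least 2-fold. Leaving out CAWS R1 replicate 2 gave 673 genes, leaving out naive R1 replicate 2 gave 698 and leaving out naive R1 replicate 3 gave 723. CAWS R1 replicate 2 also held the most Ccr2 of its group (122 CPM, the others 79.4 and 40.6).

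For R2, the Ccr2-negative, MHC-II-high macrophages, the same question was asked. The receptor kinase Ddr1, which binds collagen (gene ID 12305, chromosome 17, 35681567 to 35704741), went from 0.512 ± 0.456 to 23.8 ± 12.4 CPM (SD, n = 3). Its log2 fold change was 5.53 ± 0.64 (SE, adjusted p = 1.23e-05). Ccl22, a chemokine that draws regulatory and helper T cells (gene ID 20299, chromosome 8, 94745684 to 94751388), rose from 1.06 ± 0.215 to 20.4 ± 2.69 CPM (4.26 ± 0.25, adjusted p = 2.76e-11). Clec4e rose by 4.27 ± 0.31 (adjusted p = 3.7e-09), Adam8 by 3.92 ± 0.24 (adjusted p = 5.82e-10), and the transcription factor Bhlhe40, which GM-CSF induces, by 3.91 ± 0.50 (adjusted p = 5.32e-05). Ccr2 went from 29.3 ± 9.25 to 231 ± 31.5 CPM (2.97 ± 0.30, adjusted p = 5.4e-06). Genes that mark dendritic cells or monocytes were among the largest rises. The peptidase Dpp4 rose by 4.65 ± 0.60, the lectin Cd209a by 4.43 ± 0.66, Itgb7 by 3.70 ± 0.43 and the protease Napsa by 3.65 ± 0.51. Falls were smaller and included Ccn1 (-1.60 ± 0.29, adjusted p = 0.00109), the blood-lineage transcription factor Tal1 (-1.39 ± 0.23, adjusted p = 0.000317) and Mgl2 (-1.13 ± 0.22, adjusted p = 0.00236).

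In R2, 9 lists kept their call with an estimated correlation. Lipid-associated and repair genes rose in 15 of 29 and fell in 0 (19 and 2 adjusted over the list alone), with Lgals3 up by 2.15 ± 0.15 and the calcium-binding annexin Anxa2 by 1.53 ± 0.12. Classical monocyte markers rose in 12 of 19 and fell in 0 (17 and 0 adjusted over the list alone), with the coagulation factor F10 up by 5.22 ± 0.61 and the monocyte membrane protein Mcemp1 by 4.14 ± 0.50. These lists had medians of 0.689 and 2.92 (adjusted p = 0.00251 and 0.00408 with an estimated correlation). GM-CSF receptor and response genes rose in 9 of 23 and fell in 0 (11 and 1 adjusted over the list alone, adjusted p = 0.00106 with an estimated correlation). Extracellular matrix, protease and growth factor genes rose in 8 of 29 and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 0.00186 with an estimated correlation), with Mmp12 up by 2.10 ± 0.24. NF-kB response genes rose in 9 of 23 and fell in 1 (10 and 1 adjusted over the list alone). Fungal pattern recognition genes rose in 7 of 24 and fell in 1 (8 and 2 adjusted over the list alone). Chemokine ligands rose in 8 of 21 and fell in 1 (10 and 3 adjusted over the list alone). These 3 lists stood at adjusted p = 0.0054, 0.00476 and 0.0103 with an estimated correlation. Conventional dendritic cell markers rose in 12 of 22 and fell in 1 (15 and 1 adjusted over the list alone, adjusted p = 0.0272 with an estimated correlation). Among them the growth factor receptor Flt3 rose by 3.60 ± 0.47, while Cadm1 fell by 0.53 ± 0.12. The ninth list was glycolysis, with the rate-setting kinase Pfkp up by 0.82 ± 0.13.

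Interferon-gamma-induced genes rose in 13 of 29 in R2 and fell in 0 (18 and 1 adjusted over the list alone). Cxcl9 went from 10.1 ± 1.25 to 62.9 ± 12.8 CPM (SD, n = 3; 2.64 ± 0.19, adjusted p = 3.7e-09), and the list passed at adjusted p = 4.51e-12 (adjusted p = 0.0639 with an estimated correlation). MHC class II presentation, already high in naive R2, rose in 3 of 11 and fell in 0 (4 and 0 adjusted over the list alone). The peptide-editing chains H2-Oa and H2-DMb2 rose by 2.59 ± 0.43 and 1.89 ± 0.35, whereas H2-Ab1 did not pass (-0.29 ± 0.29, adjusted p = 0.601). The median of this list was -0.0706, its mean 0.462, and the test pointed up without passing (adjusted p = 0.221). Resident macrophage markers had 0 of 22 past the test by edgeR and 0 adjusted over the list alone, with Lyve1 at -0.89 ± 0.31 (adjusted p = 0.0777). Lyve1 did pass in R2 with limma voom (-0.87, adjusted p = 0.0219) and with only the compared groups (-0.91, adjusted p = 0.0336). In all, 1365 genes passed in R2, 901 higher and 464 lower, of which 436 and 25 changed at least 2-fold. The count was 2808 with limma voom and 2785 with only the compared groups. It was 726 without CAWS R2 replicate 2, 755 without naive R2 replicate 2, 770 without naive R2 replicate 1, 848 without naive R2 replicate 3 and 873 without CAWS R2 replicate 1. CAWS R2 replicate 2 held the most Cd209a (206 CPM) and Flt3 (49.7) of its group and CAWS R2 replicate 3 the least (69.9 and 17.4). CAWS R2 replicate 2 also gave 3.02% of its counts to a single gene ID without a symbol.

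For R3, the Ccr2-positive, MHC-II-high macrophages, the question was what CAWS changed in a population that carries the receptor of recruited cells. Chil3, a chitinase-like protein of monocytes and alternatively activated macrophages (gene ID 12655, chromosome 3, 106147554 to 106167564), rose from 3.11 ± 0.689 to 46.3 ± 19 CPM (SD, n = 3). Its log2 fold change was 3.90 ± 0.40 (SE, adjusted p = 2.61e-06). Complement factor B, Cfb (gene ID 14962, chromosome 17, 34856374 to 34862514), rose from 16.3 ± 2.82 to 145 ± 47.8 CPM (3.15 ± 0.30, adjusted p = 9.22e-07). The interferon and NF-kB kinase Ikbke rose by 2.80 ± 0.32, Fpr1, the receptor for bacterial formyl peptides, by 2.49 ± 0.23, and Mefv (pyrin), an inflammasome sensor, by 2.09 ± 0.24. Cxcl9 went from 12.3 ± 3.39 to 60.3 ± 9.22 CPM (2.29 ± 0.19, adjusted p = 5.46e-08). The largest falls exceeded those in R1 and R2. Lyve1 (gene ID 114332, chromosome 7, 110850607 to 110862953) went from 236 ± 148 to 26.8 ± 2.79 CPM (-3.13 ± 0.35, adjusted p = 1.13e-05) and Timd4 (gene ID 276891, chromosome 11, 46810786 to 46844333) from 64 ± 33 to 8.30 ± 1.74 CPM (-2.95 ± 0.32, adjusted p = 4.27e-06). Cd163, the scavenger receptor for haemoglobin (gene ID 93671, chromosome 6, 124304636 to 124330529), fell from 775 ± 223 to 182 ± 34.7 CPM (-2.09 ± 0.20, adjusted p = 3.99e-07). In naive R3, replicate 3 held the most Lyve1 (406 CPM, the others 140 and 161). Ccr2 did not pass by edgeR (0.62 ± 0.27, adjusted p = 0.133), although it did with only the compared groups (0.65, adjusted p = 0.00267) and with limma voom (0.67, adjusted p = 0.045). H2-Ab1 did not pass (-0.26 ± 0.29, adjusted p = 0.591).

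Resident cardiac macrophage markers fell in 14 of 22 genes in R3 and rose in 0 (16 and 0 adjusted over the list alone). The complement receptor Vsig4 fell by 1.94 ± 0.25, and the list had a median of -1.39 (camera adjusted p = 9.11e-11; adjusted p = 0.315 with an estimated correlation). Efferocytosis receptors and bridging molecules, with which macrophages take up dying cells, fell in 8 of 21 and rose in 1 (9 and 1 adjusted over the list alone). The scavenger receptor Cd36 went from 851 ± 177 to 240 ± 25.7 CPM (-1.83 ± 0.13, adjusted p = 2.57e-09; SD, n = 3), and the bridging proteins Mfge8 and Pros1 fell by 1.00 ± 0.11 and 0.91 ± 0.091. This was the only list past the test in R3 that kept its call with an estimated correlation (adjusted p = 0.0138). Its members Timd4, Stab1 and Gas6, all called lower, also belong to the resident list. Alternative activation genes fell in 10 of 22 and rose in 3 (10 and 3 adjusted over the list alone), Mgl2 by 1.72 ± 0.23, with Chil3 moving the other way. Cd163, Mrc1 and Ccl24 belong both to this list and to the resident list. Interferon-gamma-induced genes rose in 13 of 29 and fell in 0 (15 and 0 adjusted over the list alone), with Gbp2 up by 1.58 ± 0.20. Lipid-associated and repair genes rose in 15 of 29 and fell in 1 (17 and 2 adjusted over the list alone), with Mmp14 up by 1.65 ± 0.17. These 3 lists passed at adjusted p = 0.00119, 9.11e-11 and 6.74e-07 and lost the call (adjusted p = 0.0635, 0.24 and 0.228 with an estimated correlation). With fry they passed (adjusted p = 0.000101, 0.00253 and 0.00123), as did the resident markers (adjusted p = 0.00757). MHC class II presentation had 0 of 11 past the test by edgeR, with the invariant chain Cd74 at -0.36 ± 0.22 (adjusted p = 0.288). Complement components and receptors went both ways, 3 of 21 up and 4 down (4 and 5 adjusted over the list alone). C3, the central complement protein, rose by 1.92 ± 0.31.

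Cytosolic ribosomal protein genes rose in 12 of 43 in R3 and fell in 0 (24 and 0 adjusted over the list alone). Their median was 0.719 (adjusted p = 1.12e-11; adjusted p = 0.468 with an estimated correlation), and Rplp0, a protein of the large subunit, went from 722 ± 40.9 to 1325 ± 212 CPM (0.88 ± 0.20, adjusted p = 0.0049; SD, n = 3). These genes are short, with a median length of 740 bases against 2750 for all tested genes. The list was also higher in R1 (2 genes up and 0 down, 6 and 0 adjusted over the list alone, median 0.449, adjusted p = 0.000109; adjusted p = 0.509 with an estimated correlation) and in R2 (3 up and 0 down, 0 and 0 adjusted over the list alone, median 0.315, adjusted p = 0.00394; adjusted p = 0.639 with an estimated correlation). It took 1.07 to 1.38% of the counts in CAWS R3 and 0.712 to 0.842% in naive R3. Immediate early and dissociation stress genes, which sorting itself can induce, fell in 11 of 30 and rose in 2 (18 and 2 adjusted over the list alone). The list passed (adjusted p = 3.44e-05), lost the call with an estimated correlation (adjusted p = 0.315) and passed with fry (adjusted p = 0.00792). In R1 this list was lower too, with 4 genes down and 0 up (8 and 3 adjusted over the list alone, median -0.511, adjusted p = 8.34e-05). There it lost the call with an estimated correlation (adjusted p = 0.252) and passed with fry (adjusted p = 0.048). In R2 4 were down and 3 up (5 and 3 adjusted over the list alone, median -0.267, adjusted p = 0.0212; adjusted p = 0.491 with an estimated correlation). The growth-response factor Egr1 fell in R3 (-2.32 ± 0.67, adjusted p = 0.03), with its highest naive R3 value, 134 CPM, in replicate 3. Without that library the Egr1 call was lost (-1.62, adjusted p = 0.133), as it was without CAWS R3 replicate 1 (adjusted p = 0.073), replicate 2 (adjusted p = 0.129) or replicate 3 (adjusted p = 0.0787). Klf2, a transcription factor that restrains inflammation, fell by 1.32 ± 0.15 (adjusted p = 4.01e-06). In all, 1991 genes passed in R3, 890 higher and 1101 lower, of which 241 and 387 changed at least 2-fold. With limma voom the count was 3283. Without CAWS R3 replicate 2 the count was 973 and without CAWS R3 replicate 1 it was 1160.

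**Figure D2:**
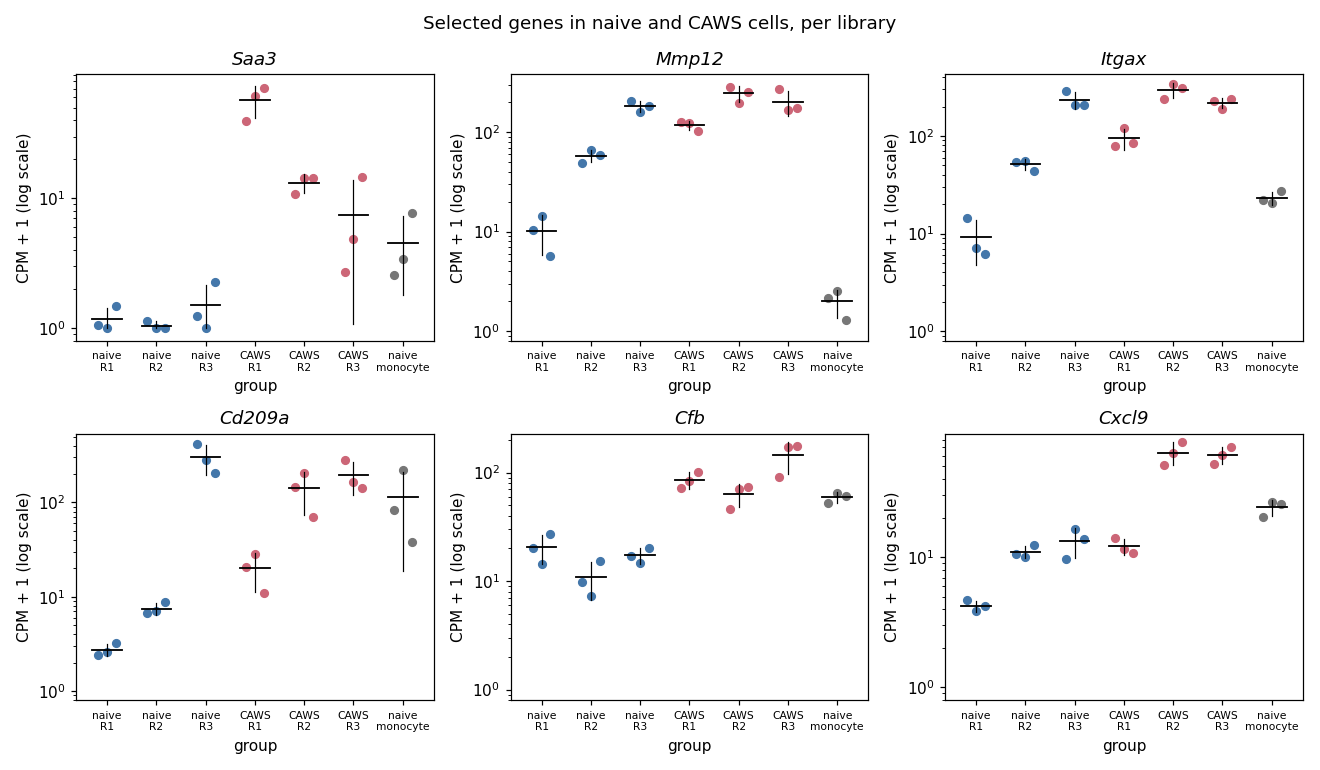
CPM plus 1 on a log scale for Saa3, Mmp12, Itgax, Cd209a, Cfb and Cxcl9 in the 7 groups; each point is a library, the horizontal line is the mean of 3 libraries and the vertical line is 1 SD to each side, ending at 0 CPM where it would go below. Mmp12 and Itgax are higher after CAWS in R1 and R2 but not in R3, and Cfb and Cxcl9 are higher in R1, R2 and R3.

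**Figure D3:**
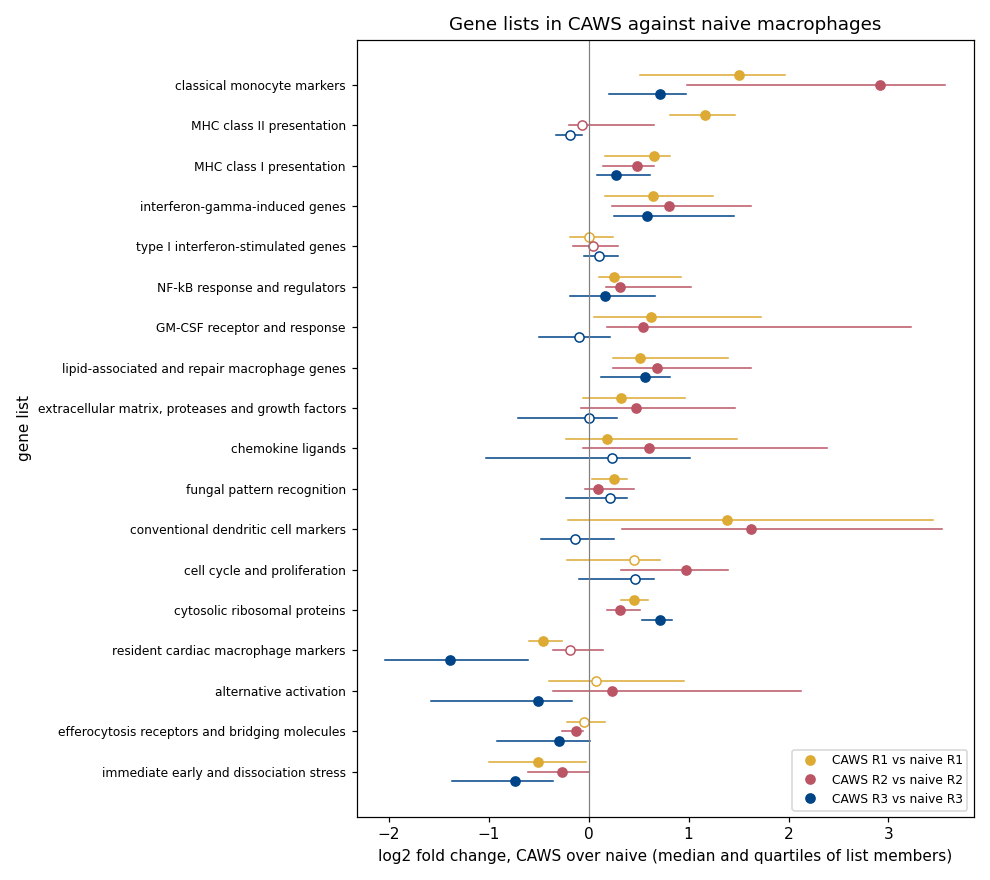
Median log2 fold change, CAWS over naive, of 18 gene lists in R1, R2 and R3, with a line from the lower to the upper quartile of the list; filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. The resident marker list has its lowest median, -1.39, in R3, and the classical monocyte list its highest, 2.92, in R2.

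The effects in the 3 populations were compared by their shared genes. Genes up in all 3 numbered 249 and genes down in all 3 numbered 124. Among the rises was Cfb (2.12 ± 0.29 in R1, 2.64 ± 0.31 in R2 and 3.15 ± 0.30 in R3). Among the falls were Mgl2 (-1.47 ± 0.22, -1.13 ± 0.22 and -1.72 ± 0.23), Klf2 (-1.06 ± 0.15, -0.83 ± 0.15 and -1.32 ± 0.15) and the splicing factor Tra2a (-1.14 ± 0.14, -1.16 ± 0.14 and -1.13 ± 0.14). Klf2 belongs to the immediate early and dissociation stress list, whose call was lost in each population with an estimated correlation (adjusted p = 0.252, 0.491 and 0.315). With fry that list was lower in R1 (adjusted p = 0.048) and in R3 (adjusted p = 0.00792). Csf1r fell in R2 (-0.30 ± 0.093, adjusted p = 0.0394) and R3 (-0.38 ± 0.093, adjusted p = 0.00854) but not past the test in R1 (-0.16 ± 0.093, adjusted p = 0.307). The Csf1r call in R2 was lost without any 1 of the 6 R2 libraries, from adjusted p = 0.0658 without naive R2 replicate 2 to adjusted p = 0.146 without naive R2 replicate 1. Adgre1 rose in R1 (0.31 ± 0.094, adjusted p = 0.039) and R3 (0.33 ± 0.094, adjusted p = 0.0208) but not past the test in R2 (0.14 ± 0.094, adjusted p = 0.387). The Adgre1 call in R1 was lost with RLE size factors (adjusted p = 0.0562), with no filter on low counts (adjusted p = 0.0662), with a stricter filter (adjusted p = 0.0612) and without any 1 of the 6 R1 libraries, the highest being adjusted p = 0.173 without naive R1 replicate 3. The Adgre1 call in R3 was lost without naive R3 replicate 1 (adjusted p = 0.0544) or replicate 2 (adjusted p = 0.0678) and without CAWS R3 replicate 2 (adjusted p = 0.151). R1 and R2 shared 445 rises where 54.7 would be expected without a relation, and 178 falls where 13.3 would be. R1 and R3 shared 331 rises (54 expected) and 194 falls (31.6 expected), and R2 and R3 shared 368 rises (60.4 expected) and 246 falls (38.5 expected). Calls in opposite directions numbered 2 (54 expected), 24 (92.4 expected) and 9 (106 expected). The 3 populations of a pool come from the same mice, so part of this overlap follows from shared pools. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.204, 0.12 and 0.147 for the 3 pairs, and shared pools alone would give 0.00988, 0.00757 and 0.0124.

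Whether CAWS acted differently in the populations was tested as the difference between their log2 fold changes (± SE). Ccr2 rose less in R3 than in R1 (-3.00 ± 0.44, adjusted p = 0.000691) and than in R2 (-2.35 ± 0.39, adjusted p = 0.00215), with its RNA already at 2390 ± 304 CPM (SD, n = 3) in naive R3. Itgax and Mmp12 behaved alike. Between R3 and R1 their differences were -3.56 ± 0.35 (adjusted p = 7.36e-06) and -3.50 ± 0.36 (adjusted p = 1.04e-05), and between R3 and R2 they were -2.66 ± 0.32 (adjusted p = 6.66e-05) and -1.95 ± 0.33 (adjusted p = 0.00169). Ccl22 rose in R2 and did not pass in R3 (-0.34 ± 0.23, adjusted p = 0.347), a difference of -4.60 ± 0.35 (adjusted p = 1.22e-08). Ddr1, Cd209a and Dpp4 responded less in R3 than in R2 as well, with differences of -5.58 ± 0.79, -5.05 ± 0.84 and -4.32 ± 0.74. Before CAWS, Cd209a and Dpp4 already stood at 204.9 to 412.9 and 28.78 to 61.03 CPM in R3. In naive R2 they stood at 5.783 to 7.712 and 0.5729 to 1.897 CPM. Itgax and Mmp12 also stood at 206.7 to 285.2 and 158.5 to 202.6 CPM in naive R3. Some resident markers fell more in R3. As a list they were lower in 4 of 22 against R1 and 6 against R2 and higher in 0 (5 and 0, and 12 and 0, adjusted over the list alone). The list passed at adjusted p = 0.000237 and 1.58e-10 and lost the call (adjusted p = 0.502 and 0.16 with an estimated correlation). Timd4 differed by -1.95 ± 0.41 against R1 (adjusted p = 0.0112) and -2.40 ± 0.41 against R2 (adjusted p = 0.00205). The Timd4 call against R1 was lost with only the compared groups (adjusted p = 0.0993) and without CAWS R3 replicate 2 (adjusted p = 0.054). Cd163 differed by -1.71 ± 0.27 (adjusted p = 0.000691) and -1.87 ± 0.27 (adjusted p = 0.00031). Lyve1 differed by -2.25 ± 0.46 (adjusted p = 0.0102) against R2 but not past the test against R1 (-1.69 ± 0.45, adjusted p = 0.0639). The Lyve1 call against R2 was lost with only the compared groups (adjusted p = 0.101) and without the 3 libraries that stood apart (adjusted p = 0.0702). Against R1 Lyve1 passed without naive R3 replicate 1 (adjusted p = 0.0146) or replicate 2 (adjusted p = 0.0357). Ms4a4a, a membrane protein of macrophages, rose more in R3 than in R1 (1.31 ± 0.20, adjusted p = 0.000517) and than in R2 (1.19 ± 0.20, adjusted p = 0.00143). For H2-Ab1 0 of the 3 differences passed the test by edgeR (adjusted p = 0.391, 0.107 and 0.991). With the pool as a block within each treatment its response was smaller than that of R1 in R2 (-1.42, adjusted p = 2.19e-08) and in R3 (-1.35, adjusted p = 7.72e-09).

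In the fit without a pool term, 7 genes differed in their response between R2 and R1 (edgeR, against 702 at an unadjusted p under 0.05). Of these, 5 had the larger log2 fold change in R2 and 2 the smaller. The glucocorticoid-induced annexin Anxa1 (gene ID 16952, chromosome 19, 20373434 to 20390671) rose by 0.75 ± 0.12 in R1 and by 1.93 ± 0.12 in R2, a difference of 1.19 ± 0.17 (adjusted p = 0.00579). Anxa2, the heparan-cutting enzyme Hpse and the membrane receptor Cd300lg differed by 0.93 ± 0.17, 1.64 ± 0.29 and 1.93 ± 0.32. Cadm1 (gene ID 54725, chromosome 9, 47530170 to 47862280) rose in R1 (0.58 ± 0.12, adjusted p = 0.00406) and fell in R2 (-0.53 ± 0.12, adjusted p = 0.00484), a difference of -1.11 ± 0.17 (adjusted p = 0.00839). Mpeg1, the pore-forming protein perforin-2, differed by -0.83 ± 0.15. The seventh gene, the cell cycle regulator Ccne1 (3.99 ± 0.71, adjusted p = 0.026), lies below the expression that the rule for named genes asks for and was chosen after its values were seen. With 1 library left out, Cadm1 lost its call without CAWS R2 replicate 2 (adjusted p = 0.0528). Anxa2, Hpse, Cd300lg, Mpeg1 and Ccne1 lost theirs without any of several libraries, the highest being adjusted p = 0.157, 0.12, 0.0828, 0.138 and 0.138. Leaving out CAWS R2 replicate 2 gave 1 gene, naive R1 replicate 3 or naive R2 replicate 1 gave 2, and naive R2 replicate 2 or naive R2 replicate 3 gave 3. Leaving out CAWS R1 replicate 1 gave 4 and CAWS R1 replicate 2 gave 11. With the pool as a block within each treatment the count was 130.

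The lists were compared in the same way. Lower and higher here refer to the log2 fold change after CAWS, not to the level of RNA. GM-CSF receptor and response genes responded less in R3 than in R1 (1 of 23 genes lower and 0 higher, 3 and 0 adjusted over the list alone). Against R2 they did so too (8 lower and 0 higher, 8 and 0 adjusted over the list alone), and both calls held (adjusted p = 0.0145 and 0.000121 with an estimated correlation). Conventional dendritic cell markers were lower in 4 of 22 against R1 and 9 against R2 and higher in 0 (8 and 0, and 14 and 0, adjusted over the list alone), at adjusted p = 0.0385 and 0.00693 with an estimated correlation. In naive cells the dendritic cell list already stood higher in R3 than in R1 (median log2 fold change 3.03, or 2.71 with genes without a count at their floor). The GM-CSF list stood higher in naive R3 than in naive R2 (median 0.733). Extracellular matrix, protease and growth factor genes were lower in 6 of 29 and higher in 1 against R1, and lower in 6 and higher in 0 against R2 (7 and 1, and 9 and 1, adjusted over the list alone), at adjusted p = 0.00807 and 0.000538 with an estimated correlation. Efferocytosis genes fell more in R3 than in R1 (6 of 21 lower and 0 higher, 6 and 0 adjusted over the list alone, adjusted p = 0.00807 with an estimated correlation), Cd36 by 1.61 ± 0.17. Against R2 the efferocytosis list was lower in 5 and higher in 0 (adjusted p = 0.0108) and lost the call (adjusted p = 0.0556 with an estimated correlation). Alternative activation genes had a lower CAWS effect in R3 than in R2 (7 of 22 lower and 0 higher, 7 and 0 adjusted over the list alone, adjusted p = 0.000121 with an estimated correlation), with Cd163 among them. Against R1 they were lower in 2 and higher in 0 (adjusted p = 0.0196) and lost the call (adjusted p = 0.12 with an estimated correlation). Ccl17, Ccl22, Ccl24, Irf4 and Mrc1 are among the genes this list shares with the GM-CSF list. The GM-CSF list shares Itgax, Cd209a and Irf4 with the dendritic cell list. The CAWS effect on MHC class II presentation was lower as a list in R3 than in R1 (median -1.31, adjusted p = 4.43e-09, and adjusted p = 0.12 with an estimated correlation). There 1 of 11 genes passed, Ciita at -1.31 ± 0.25 (10 and 0 adjusted over the list alone). The level of H2-Ab1 stayed higher in R3, at 8530 to 12320 CPM in CAWS R3 and 990.7 to 1617 in CAWS R1. The response of heart tissue markers was lower against R1 as well. Cardiomyocyte markers were lower in 7 of 22 and higher in 0 (11 and 0 adjusted over the list alone, adjusted p = 1.38e-09; adjusted p = 0.0728 with an estimated correlation). Smooth muscle and pericyte markers were lower in 2 of 11 and higher in 0 (2 and 0 adjusted over the list alone, adjusted p = 4.58e-05; adjusted p = 0.237 with an estimated correlation). Against R2 the cardiomyocyte, smooth muscle and pericyte, fibroblast and endothelial lists were lower too (adjusted p = 0.00455, 0.00613, 0.00111 and 0.0205). All of them lost the call (adjusted p = 0.366, 0.379, 0.381 and 0.181 with an estimated correlation). The genes past the test numbered 300 between R3 and R1 (13 higher, 287 lower) and 309 between R3 and R2 (13 higher, 296 lower), and 902 and 814 with the pool as a block within each treatment. DESeq2 gave 479 for the first and limma voom 623 for the second. Without CAWS R3 replicate 2 they numbered 180 and 188. The first count was 182 without CAWS R3 replicate 1 and 187 without naive R1 replicate 3, and the second was 199 without CAWS R2 replicate 2.

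The naive populations were compared with each other to describe the cells before CAWS. Between R2 and R1 the MHC class II genes differed most, as a sort on MHC-II would give. H2-Ab1 was higher in R2 by 4.13 ± 0.33 (adjusted p = 3.38e-07) on the log2 scale (SE), H2-Eb1, another class II beta chain, by 4.81 ± 0.44, and 11 of 11 genes of the list passed (11 and 0 adjusted over the list alone, adjusted p = 9.82e-05 with an estimated correlation). R1 held more Aqp1, a water channel (35.6 ± 3.82 CPM against 3.32 ± 0.529, SD, n = 3; -3.42 ± 0.22, adjusted p = 1.13e-09), and more Vsig4 (289 ± 67.2 against 53.5 ± 15.2; -2.43 ± 0.22, adjusted p = 1.32e-07). In R3 against R1, the sorting marker Ccr2 was higher by 8.51 ± 0.39 and Itgax by 4.77 ± 0.28. Resident markers were lower in 20 of 22 genes and higher in 0 (20 and 0 adjusted over the list alone, adjusted p = 0.0419 with an estimated correlation). Dendritic cell markers were higher in 14 of 22 and lower in 0 (16 and 0 adjusted over the list alone, adjusted p = 0.0132 with an estimated correlation). In R3 against R2, the matrix protein Fn1 went from 18.8 ± 7.33 to 725 ± 289 CPM (5.26 ± 0.44, adjusted p = 8.54e-07). Classical monocyte markers were higher in 14 of 19 and lower in 0 (14 and 0 adjusted over the list alone, adjusted p = 0.00366 with an estimated correlation). The counts were 946 for R2 against R1 (515 higher, 431 lower), 3074 for R3 against R1 (1660 and 1414) and 1646 for R3 against R2 (880 and 766). With the pool as a block the first and the third were 1989 and 3153, and with only the compared groups the first was 1531. The first was 588 without naive R2 replicate 1, 595 without naive R1 replicate 3 and 602 without naive R2 replicate 2. The third was 1060 without naive R2 replicate 3 and 1075 without naive R3 replicate 1.

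After CAWS the same populations were compared again. R2 still exceeded R1 in 11 of 11 MHC class II genes (11 and 0 adjusted over the list alone, adjusted p = 0.000126 with an estimated correlation). A sort on MHC-II would give this too. H2-Ab1 was higher by 2.74 ± 0.31 (adjusted p = 4.33e-05) on the log2 scale (SE), Ccl22 by 4.72 ± 0.27 (adjusted p = 1.72e-11) and Ccr2 by 1.53 ± 0.28 (adjusted p = 0.0041). The Ccr2 call was lost with only the compared groups (1.52, adjusted p = 0.18). Saa3 was lower in R2 than in R1, 12.2 ± 2.12 against 56.3 ± 15.9 CPM (SD, n = 3; -2.20 ± 0.39, adjusted p = 0.00109), a call lost for Saa3 with DESeq2 (-2.21, adjusted p = 0.369) and with the older edgeR fit (adjusted p = 0.0845). Dendritic cell markers were higher in R2 than in R1 in 16 of 22 genes and lower in 0 (17 and 0 adjusted over the list alone, adjusted p = 0.001 with an estimated correlation). In R3 against R1, the sorting marker Ccr2 was higher by 5.51 ± 0.33 and Chil3 by 4.41 ± 0.41, while Lyve1 was lower by 4.30 ± 0.36 (adjusted p = 1.01e-07). There 20 of 22 resident markers were lower and 0 higher (21 and 0 adjusted over the list alone, adjusted p = 0.0476 with an estimated correlation). In R3 against R2, the calcium-binding protein Cpne8 was lower by 3.61 ± 0.22 and the inflammasome sensor Mefv higher by 2.75 ± 0.26. Efferocytosis genes were lower in 10 of 21 and higher in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.00277 with an estimated correlation). The counts were 501 for R2 against R1 (327 higher, 174 lower), 3907 for R3 against R1 (1737 and 2170) and 2027 for R3 against R2 (732 and 1295). With the pool as a block the first and the third were 1353 and 3532, and with limma voom they were 790 and 3939. With only the compared groups the first was 794. The first was 227 without CAWS R2 replicate 2, 247 without CAWS R1 replicate 1 and 280 without CAWS R1 replicate 3. The third was 1236 without CAWS R3 replicate 1, 1283 without CAWS R3 replicate 2 and 1311 without CAWS R2 replicate 3.

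The cardiac populations were set against splenic monocytes, a blood-derived cell from another organ, so that tissue and cell type differ together. The first component of complement marked the macrophages. C1qb, a chain of complement C1q, measured 2747 ± 75.9 CPM in naive R1, 2333 ± 62.8 in naive R3 and 2426 ± 180 in CAWS R3 against 8.26 ± 2.63 in the monocytes (SD, n = 3). It was higher by 8.39 ± 0.16, 8.16 ± 0.16 and 8.21 ± 0.16 on the log2 scale (SE). The receptor Mertk for dying cells was higher by 7.27 ± 0.21 in naive R1, 6.48 ± 0.22 in naive R3 and 6.35 ± 0.22 in CAWS R3. The monocytes held more Ly6c2, the antigen of classical monocytes, 863 ± 148 CPM against 2.94 ± 1.49 in naive R3 and 6.91 ± 0.317 in CAWS R3 (-8.18 ± 0.24 and -6.96 ± 0.22). Efferocytosis genes were higher in 15 of 21 and lower in 4 in naive R1, 15 and 4 in naive R2, 13 and 4 in naive R3 and 12 and 3 in CAWS R3. Adjusted over the list alone the counts were 15 and 4, 16 and 5, 13 and 4, and 12 and 4, and all 4 calls held (adjusted p = 7.07e-05, 4.73e-05, 4.03e-05 and 4.14e-05 with an estimated correlation). Classical monocyte markers were lower in 19, 19, 18 and 18 of 19 genes in the same 4 comparisons and higher in 0. Adjusted over the list alone the counts were 19 and 0, 19 and 0, 18 and 0, and 18 and 0 (adjusted p = 0.0232, 0.0135, 0.0219 and 0.0191 with an estimated correlation). The genes past the test numbered 8401 for naive R1 (4318 higher, 4083 lower), 8440 for naive R2 (4390 and 4050), 7825 for naive R3 (4229 and 3596) and 6322 for CAWS R3 (3297 and 3025). Monocyte replicate 2 gave 2.17% of its counts to ribosomal protein genes, and the other monocyte libraries 1.02 and 1.13%.

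Whether CAWS moved each population towards or away from the monocytes was asked with 200 genes higher and 200 genes lower in monocytes, each set chosen from the other naive populations. The genes higher in monocytes rose in all 3 populations. In R1, 59 rose and 4 fell (median log2 fold change 0.348, adjusted p = 0.0134 with an estimated correlation). In R2, 80 rose and 3 fell (0.398, adjusted p = 0.00235 with an estimated correlation), and in R3, 78 rose and 2 fell (0.404, adjusted p = 0.00632 with an estimated correlation). The genes lower in monocytes had their lowest median in R3, -0.615, where 129 fell and 7 rose (adjusted p = 0.000103 with an estimated correlation). In R2 the median was -0.225, with 49 down and 13 up (adjusted p = 0.0182 with an estimated correlation). In R1 it was -0.0876, with 34 down and 23 up (adjusted p = 0.0184; adjusted p = 0.312 with an estimated correlation). A difference between the populations in these sets was not tested. Of the single monocyte genes, Ly6c2 stood at 6.91 ± 0.317 CPM in CAWS R3 against 863 ± 148 in the monocytes and Chil3 at 46.3 ± 19 against 1268 ± 396, while Ccr2 stood at 3667 ± 343 against 3262 ± 313 (SD, n = 3).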

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

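Each result here is a CAWS effect that differed between populations by the interaction test, and the tests and lists were fixed before the data were examined. Between R2 and R1, 7 genes and 9 lists passed, of which 1 list held with an estimated correlation and 0 with fry, and 59 of 100 splits of the libraries reached 9 lists. Those splits relabelled each population on its own and give no chance rate. With the pool as a block nested within treatment the gene counts were 130 between R2 and R1, 902 between R3 and R1 and 814 between R3 and R2. Cd300lg (1.93), Hpse (1.64), Anxa1 (1.19) and Anxa2 (0.93) rose more in R2, while Cadm1 (-1.11) and Mpeg1 (-0.83) moved lower there. Of these Cd300lg, Hpse, Anxa2, Cadm1 and Mpeg1 lost their calls with 1 library left out, the highest being adjusted p = 0.0828, 0.12, 0.157, 0.0528 and 0.138. Alternative activation genes had a median difference of 0.359. Between R3 and R1, 300 genes and 17 lists passed, of which 4 lists held with an estimated correlation. Ms4a4a (1.31), Hpse (1.27), Nxpe5 (0.87), AB124611 (0.81), Clec4n (0.80) and Dok2 (0.71) responded more in R3. Clec4n lost its call in 10 settings and Nxpe5 in 5, the highest for both being without CAWS R3 replicate 2 (adjusted p = 0.129 and 0.0874). Itgax (-3.56), Mmp12 (-3.50), Hs3st3a1 (-3.03), Ccr2 (-3.00), Klrb1b (-2.97) and Adam8 (-2.36) responded less. The Klrb1b call was lost without CAWS R1 replicate 2 (-2.08, adjusted p = 0.163), with limma voom (adjusted p = 0.221), with only the compared groups (adjusted p = 0.0783) and with the nested block (adjusted p = 0.0547). The median differences of the lists that held with an estimated correlation were -0.584 for GM-CSF receptor and response, -0.281 for efferocytosis, -0.769 for extracellular matrix, proteases and growth factors and -1.38 for conventional dendritic cell markers. Without the 3 dendritic cell markers that had no count in a group their median was -1.09. Between R3 and R2, 309 genes and 24 lists passed, of which 5 lists held with an estimated correlation. Tmem38b (1.27), Icam2 (1.19), Ms4a4a (1.19), Cd276 (0.82), AB124611 (0.73) and Tlr1 (0.72) responded more in R3. Icam2 lost its call in 11 settings (highest adjusted p = 0.156, without naive R2 replicate 2), Tmem38b in 8 (0.152, without naive R2 replicate 3) and Cd276 in 6 (0.0882, without naive R2 replicate 1). Without CAWS R3 replicate 2 the calls of Tlr1 (adjusted p = 0.0845) and AB124611 (adjusted p = 0.0735) were lost. Ddr1 (-5.58), Cd209a (-5.05), Ccl22 (-4.60), Jaml (-4.36), Dpp4 (-4.32) and Hr (-4.31) responded less. Of these, Cd209a and Dpp4 already stood at 204.9 to 412.9 and 28.78 to 61.03 CPM in naive R3. The median differences were -0.785 for GM-CSF receptor and response, -0.962 for alternative activation, -0.245 for complement, -0.79 for extracellular matrix, proteases and growth factors and -1.41 for dendritic cell markers. Without the 1 GM-CSF gene that had no count in a group the median of its list was -0.718.

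The tests of this pattern were fixed before their values were seen. Genes that rose in R1 and R2 after CAWS include markers of the Ccr2-positive cells, so cells of the R3 gate carried into the R1 and R2 sorts were weighed. If Ccr2 RNA in the highest library is read as carried cells, they make up 3.14% of the RNA in R1 and 6.52% in R2. Of the rising genes, 99.9% in R1 and 99.8% in R2 rose by more than that share of the gap between CAWS R3 and the naive population. For genes little higher in CAWS R3 this bound is too small to tell much. In R1 196 and in R2 270 rising genes were at least 4-fold higher in CAWS R3 than in the naive population. Of these, 1 and 2 stayed at or under the Ccr2 share, and their median implied shares were 34.5% and 58.8%. Carried cells with the mean Ccr2 RNA of their gate are thus unlikely to account for the whole pattern. R1 and R2 were sorted as Ccr2-negative, so carried cells could hold less Ccr2 RNA, and the bound cannot decide on such cells. By mean CPM, 305 rising genes in R1 and 333 in R2 stood higher than in CAWS R3. A mixture with cells of the mean CAWS R3 profile could not give those rises. The rise of Ccr2 itself stays open.

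For the ribosomal protein genes higher in CAWS R3, the test of gene length as the whole of the difference was chosen only after the result was seen, and the others were fixed before. With each library's trend on gene length removed, the list median went from 0.719 to 0.345, so length bias could account for part of it. In the fit with that correction 14 members were called higher, against 12 without it, and whether they were the same genes was not recorded. With every library thinned to the smallest total count the median was 0.729. Thinning leaves the ratios of well-counted genes nearly as they were, so this test could not decide on library depth. The call was lost with an estimated correlation before any correction (adjusted p = 0.468 with an estimated correlation).

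For the resident markers lower in CAWS R3, the second test of lost R1 and R2 cells and its condition on the rank correlation were chosen only after the first result was seen. R1 and R2 cells inside the naive R3 gate could make up at most 12.2% and 33% of its RNA, and only 1 of the 14 called resident markers fell below the level left without them, so this explanation stays open. Other genes low in naive R3 had a median change of -1.07 where the fitted shares of such cells predicted -1.4, with a Spearman rho of 0.18 between predicted and observed changes (highest with genes shuffled 0.443), which leaves it undecided. Dilution by cells with the profile of splenic monocytes would need 63.4% monocyte RNA. The 200 genes higher in monocytes implied 7.81%, so dilution of that kind is unlikely to be the cause.

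The same libraries were also divided into other groups of the same sizes, as planned before the results were seen. With 10 splits a share under 0.05 is out of reach, so only the real and the highest other value are given for those comparisons. For genes, 1 of 10 splits, the real one, reached the count for CAWS against naive cells in R1 (1187, highest other 2), R2 (1365, highest other 0) and R3 (1991, highest other 1). The same held between naive populations for R2 and R1 (946, highest other 0), R3 and R1 (3074, highest other 1) and R3 and R2 (1646, highest other 2). It held between CAWS populations for R2 and R1 (501, highest other 0), R3 and R1 (3907, highest other 0) and R3 and R2 (2027, highest other 0). Against monocytes it held for naive R1 (8401, highest other 1), naive R2 (8440, highest other 0), naive R3 (7825, highest other 4) and CAWS R3 (6322, highest other 1386). For the interactions, 9 of 100 splits reached 7 genes between R2 and R1 (highest other 503), 4 of 100 reached 300 between R3 and R1 (highest other 3003) and 13 of 100 reached 309 between R3 and R2 (highest other 3434). Here each population was relabelled on its own. A split can thus keep or reverse the CAWS effect in 1 population alone, which creates a difference between the populations. The share of such splits gives no chance rate for the interactions. Splits that keep whole pools together gave at most 0, 2 and 0 genes. These splits mix CAWS and naive libraries alike in both populations. The shared CAWS effect then cancels in the difference and widens the spread within groups. Few calls would follow from that alone, so these counts give no chance rate either.

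For gene lists the real count of 26 in R1 was reached by 1 of 10 splits (highest other 16), 26 in R2 by 1 of 10 (23) and 14 in R3 by 3 of 10 (17). Between naive populations 21 for R2 and R1 was reached by 1 of 10 (15), 21 for R3 and R1 by 2 of 10 (23) and 21 for R3 and R2 by 2 of 10 (23). Between CAWS populations 21 for R2 and R1 was reached by 1 of 10 (18), 18 for R3 and R1 by 2 of 10 (18) and 13 for R3 and R2 by 3 of 10 (16). Against monocytes 22 for naive R1, 23 for naive R2, 24 for naive R3 and 26 for CAWS R3 were reached by 1 of 10 each (16, 15, 18 and 22). For the interactions 9 lists between R2 and R1 were reached by 59 of 100 splits (26), 17 between R3 and R1 by 16 of 100 (27) and 24 between R3 and R2 by 4 of 100 (25). These splits again relabelled each population on its own, so their share gives no chance rate. Counts of lists at the preset correlation were thus reached by other splits in several comparisons, and splits that keep whole pools together gave up to 6, 9 and 13 lists in the interactions. For the reason given for genes, the splits of whole pools give no chance rate for lists either.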

How the results depend on the processing

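Most settings were fixed before the data were examined, and leaving out 3 libraries together was chosen after they were seen to stand apart. The deposited per-sample counts were identical to the table used for 21 of 21 libraries. A result is called moved if a count changed more than 1.5-fold, and the cause was not tested for those that did not hold. The number of genes whose CAWS effect differed between R2 and R1, 7, was the least stable. It was 14 with no filter on low counts, 12 with the older edgeR fit, 57 with DESeq2, 22 with limma voom and sample weights, 33 with only the compared groups, 23 with a replicate block, 130 with that block nested within treatment and 18 without the 3 libraries. DESeq2 gave 479 genes for R3 against R1 in place of 300. Limma voom gave 623 for the R3 and R2 interaction, 2808 for CAWS in R2, 3283 for CAWS in R3, and in CAWS cells 790 for R2 against R1 and 3939 for R3 against R2. Only the compared groups gave 2785 for CAWS in R2, 1531 for naive R2 against R1 and 794 for CAWS R2 against R1. The nested block gave 902 and 814 for the R3 interactions, 1989 and 3153 for naive R2 against R1 and R3 against R2, and 1353 and 3532 for the same in CAWS cells. For comparisons without paired pools the plain replicate block gave 1398, 1618 and 2302 genes for CAWS in R1, R2 and R3, and against monocytes 8567, 8595 and 7994 for naive R1, R2 and R3 and 6563 for CAWS R3.

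With 1 library left out at a time, which leaves a pair in its group, the CAWS counts ran from 673 to 893 in R1, from 726 to 1022 in R2 and from 973 to 1887 in R3. The interactions ran from 1 to 11 for R2 and R1, from 180 to 299 for R3 and R1 and from 188 to 314 for R3 and R2. In naive cells the counts ran from 588 to 805 for R2 and R1, from 2410 to 3013 for R3 and R1 and from 1060 to 1620 for R3 and R2. In CAWS cells they ran from 227 to 458, from 2823 to 3736 and from 1236 to 1912. Against monocytes they ran from 7949 to 8179 for naive R1, from 7767 to 8153 for naive R2, from 7263 to 7626 for naive R3 and from 5534 to 6287 for CAWS R3.

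The number of gene lists fell in every comparison with an estimated correlation. For CAWS it went from 26, 26 and 14 to 5 in R1, 9 in R2 and 1 in R3, and for the interactions from 9, 17 and 24 to 1 for R2 and R1, 4 for R3 and R1 and 5 for R3 and R2. For R2 and R1, R3 and R1, and R3 and R2 it became 1, 5 and 6 in naive cells and 5, 3 and 2 in CAWS cells. Against monocytes it became 7 for naive R1, 3 for naive R2, 4 for naive R3 and 7 for CAWS R3. Fry gave 0 lists for the R2 and R1 interaction and 39 for each naive population against monocytes. For CAWS against naive cells fry gave 30 lists in R1, 26 in R2 and 16 in R3. It gave 15 lists for the R3 and R1 interaction and 17 for R3 and R2. Without CAWS R2 replicate 1 the R2 and R1 interaction gave 14 lists in place of 9. The R1 fall of genes lower in monocytes lost its call at an unchanged median of -0.0876 with an estimated correlation (adjusted p = 0.312), and also with sets of 100 genes (-0.0528) and with larger sets (-0.0594), and its median ran from -0.131 to -0.063 with 1 R1 library left out. The CAWS calls shared by R1 and R2, R1 and R3, and R2 and R3 numbered 233, 198 and 246 at an adjusted p under 0.01, 163, 95 and 117 with a 2-fold change, and 798, 661 and 750 with DESeq2.

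Of the values for named genes across settings, 2649 stayed called or not called as before, 138 lost a call, 11 gained one and 3 changed sign. The sign changes were all in the H2-Ab1 difference between R3 and R2, which stayed far from the test and ran from -0.0864 to 0.152 with 1 library left out, with -0.0385 and -0.0572 in the other libraries that changed its sign. Icam2, Clec4n, Adgre1 in R1 and Anxa2 lost their calls most often. H2-Ab1 in R1 lost its call in 7 settings, Klrb1b in 7 and Egr1 in 6. Ccr2 in R3 passed with only the compared groups (0.65, adjusted p = 0.00267) and with limma voom (0.67, adjusted p = 0.045).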

Other observations

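Glycolysis, cell cycle and cholesterol synthesis genes were also followed in R2 after CAWS. Glycolysis genes rose in 9 of 21 and fell in 0 (11 and 1 adjusted over the list alone), with the kinase Pfkp up by 0.82 ± 0.13 (SE, n = 3). Cell cycle genes rose in 9 of 40 and fell in 0 (22 and 0 adjusted over the list alone), among them the mitotic motor Kif20a (1.64 ± 0.32, adjusted p = 0.00173) and the survivin gene Birc5 (1.60 ± 0.33, adjusted p = 0.00286). Cholesterol synthesis genes rose in 7 of 22 and fell in 0 (8 and 0 adjusted over the list alone), with the decarboxylase Mvd up by 1.43 ± 0.21 (adjusted p = 9.58e-05). The glycolysis list held with an estimated correlation (adjusted p = 0.022), and the other 2 did not (adjusted p = 0.405 and 0.26 with an estimated correlation). As lists, glycolysis and cell cycle genes responded less in R3 than in R2 at the preset correlation (adjusted p = 0.0405 and 0.0203) and lost that call (adjusted p = 0.273 and 0.681 with an estimated correlation). Between R2 and R1 the cell cycle list passed (adjusted p = 1.1e-07) and lost the call (adjusted p = 0.593 with an estimated correlation), and the glycolysis list did not pass (adjusted p = 0.0586). The cholesterol synthesis list passed neither against R1 (adjusted p = 0.395) nor against R3 (adjusted p = 0.0519).

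Few type I interferon-stimulated genes passed the test after CAWS. By edgeR 0 of 34 passed in R1, 1 in R2 and 1 in R3, the 1 being the DNA-sensing gene Ifi205 in both (2.73 ± 0.32, adjusted p = 5.4e-06 in R2 and 1.47 ± 0.25, adjusted p = 0.000396 in R3). Adjusted over the list alone the rises and falls were 0 and 0, 1 and 0, and 1 and 0, and the medians were 0.000125, 0.0413 and 0.107.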
